A study of Homo sapiens and Mus musculus with 16 samples.

How the data were processed

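Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters preferentially into open DNA, in K562 cells, a human erythroleukaemia line. Per the labels, 50000 cells per library were collected after 4 days of doxycycline at 1 µg/ml, which induced the modified allele, from cells with wild-type (WT) SF3B1 and cells with the K700E substitution in SF3B1, a subunit of the U2 snRNP that recognises the branch point during splicing. Each genotype had 2 libraries. The labels also list human CD34+ and mouse progenitor samples, which were not analysed here.

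Each library came as 1 list of accessible islands with its own coordinates, so islands were called per library and not on pooled reads. Per the submitters' processing notes, Bowtie2, SICER, DESeq2 and the hg38 build were used, without versions or roles. How the reads were filtered, whether duplicates were removed and whether read positions were shifted for the transposase is not given in the sources used here. Per the file headers, the authors deposited the position, a read count and a score for every island. The read count is a whole number of reads of that library inside the island, not normalized. The score deposited by the authors is the caller's own value for the island; it was used here only to break ties in ranking islands within 1 list. Every island was a whole number of 200 bp windows, and islands of 1 list were at least 800 bp apart. Positions are given 1-based on hg38.

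Island reads on the autosomes and the X chromosome numbered 21597064 and 12713667 in the WT libraries and 24393587 and 19468530 in the K700E libraries. The total reads of the libraries are unknown, since only reads inside islands were counted. The weakest island held 28 and 17 reads in the WT libraries and 27 and 26 in the K700E libraries, so absence from a list means fewer reads than the caller required and not an absence of reads.

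Genes came from the RefSeq table of GRCh38.p14, the same build as hg38, with 19970 protein-coding genes on the autosomes and X. The table holds no strand, transcripts or exons, so the promoter windows planned were replaced by gene-end windows of 1 kb either side of both ends of a gene, and exons, introns and a single start site per gene were not analysed. A gene-end island therefore lies at the start or at the end of a gene. Genes known mainly from alternate haplotypes can carry positions that do not belong to the main chromosome, and this could not be checked.

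Lists were compared by overlap of at least 1 bp. For the location of islands and regions in the lists, only those with their midpoint in a gene-end window counted as lying at a gene end. For genes, and for gene-end islands in the count comparison below, any overlap with a window was enough. The reads given for a gene are those of its strongest gene-end island in that library, which can lie at either end of the gene. The 4 lists were merged into union regions, and a region or gene end was called K700E-only when both K700E libraries and no WT library held it, and WT-only in the opposite case. The 4 pairs that mix the genotypes served as the background. Group differences were tested with an exact two-sided permutation test over the 6 assignments of 4 libraries, whose smallest possible p is 0.333, so no such comparison could pass a threshold of 0.05. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries. Similarity was the Jaccard index in base pairs.

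The 18 gene lists were fixed before the data were examined: erythroid, megakaryocyte, granulocyte and monocyte, stem and progenitor, genes mis-spliced with mutant SF3B1, replication, replication stress and repair, R-loop, elongation, splicing, H3K4 methylation, SIN3 and HDAC, ribosomal proteins, interferon and inflammation, lymphocyte, epithelial, hepatocyte and neuron. Of their members, 637 matched a gene and 1 did not. Fisher's exact test, two-sided, compared each list with other genes in both directions, with Benjamini-Hochberg adjustment over 36 tests. The genes named were set by a rule fixed at the same time: the K700E-only and WT-only members of each list, up to 4 per direction, or else up to 2 members in list order; the 10 K700E-only and 10 WT-only genes with the highest within-list percentile of reads; GATA1, HBG1, SF3B1 and GAPDH; and 3 regions per direction outside gene ends. Other genes named were chosen after their values were seen, and the text says so. A gene that the rule names is not reported here.

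A count test had been planned only for counts over common regions. Because the lists carry raw counts, a count comparison was added after the data had been seen, on the 32604 islands that correspond 1 to 1 in the 4 lists. Each library's count refers to the extent of its own island, which differs between libraries. These counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr and Benjamini-Hochberg adjustment, and gene lists were tested over gene-end islands with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. DESeq2 1.42.0, scaling to the total, loess offsets, regional offsets from 5 Mb bins, islands whose extents match by at least 80%, all regions of the 4 lists, a fit without chromosomes 3, 10 and 12, the replicate block and leaving out each library were the alternatives. The library total used for scaling and for CPM was that of the tested islands, not of all islands. In data simulated from the real means for K700E against WT on 32604 islands, edgeR recovered 99% of planted changes of log2 size 2 and 30% of those of log2 size 1, and called 8 unchanged islands. The overlap code recovered all 5250 planted regions.

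For the lists, the alternatives were equal numbers of islands per list, the stronger part of each list, all sequences in the files, islands of at least 400 bp, a stricter overlap, merging within 1 kb, gene-end windows of 500 bp and 2 kb, the replicate block and leaving out each library; a floor of 2 RPM (reads scaled to the island reads of the library) and whole gene bodies were added after the data had been seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.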

Results

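The series concerns how splicing factor mutations affect transcription elongation, replication stress and chromatin. Accessible chromatin was compared between K562 cells with WT SF3B1 and with SF3B1 K700E, a substitution found in myelodysplastic syndrome, with 2 libraries each. The WT libraries held 82012 and 81251 islands and the K700E libraries 104698 and 91596 islands on the autosomes and X.

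K700E libraries held more islands, and their islands covered more of the genome. The mean was 98147 ± 9265 islands (SD, n = 2) in K700E and 81631.5 ± 538 (SD, n = 2) in WT, a ratio of 1.20, and both K700E libraries lay above both WT libraries (exact two-sided permutation p = 0.333, the smallest possible). The covered length was 344.1 ± 6.56 Mb in K700E and 253.4 ± 57.7 Mb in WT (SD, n = 2; exact permutation p = 0.333). The difference in islands, 16515.5, was 9964.5 without K700E replicate 1. The difference in covered length, 90670400 bp, was 49885000 bp without WT replicate 2 and 131456000 bp without WT replicate 1. The number of reads in islands overlapped between genotypes: WT replicate 1 held 21597064 and K700E replicate 2 held 19468530, and WT replicate 1 had fewer islands. Reads per kb of covered sequence were 73.4 and 59.8 in WT and 71.9 and 55.8 in K700E. The mitochondrial share of all reads in islands was lower in both K700E libraries, 5.02% and 5.86%, than in both WT libraries, 6.55% and 9.34% (exact permutation p = 0.333).

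A smaller share of islands had their midpoint at a gene end in K700E. Such islands made up 9.16% of islands in each K700E library and 10.8% and 12.5% in the WT libraries, a difference of -2.53 percentage points (exact permutation p = 0.333). A share by midpoint can depend on island width. The median width was 2600 and 2000 bp in the WT libraries and 2200 and 2800 bp in the K700E libraries. The difference was -1.26 points with equal numbers of islands, -4.99 points in the stronger part of each list and -1.68 points without WT replicate 2. Islands inside protein-coding genes were 38.3% ± 0.482 in K700E and 36.3% ± 0.886 in WT, and intergenic islands 38.9% ± 0.301 and 38.0% ± 0.514 (SD, n = 2).

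**Figure D1:**
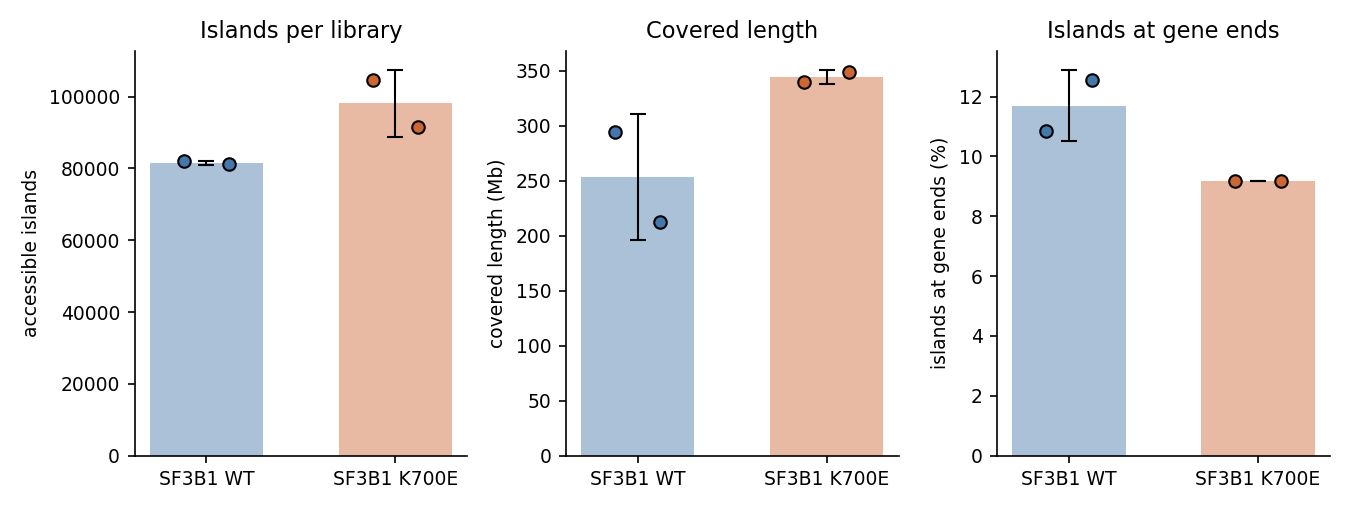
Number of islands, covered length in Mb and percentage of islands with their midpoint at a gene end in each library (points). Bars give the mean and error bars the SD of the 2 libraries per genotype. Both K700E libraries, at 104698 and 91596 islands, lie above both WT libraries.

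Of 115221 union regions, 48388 were present in all 4 libraries. K700E-only regions numbered 8213 and WT-only regions 1620, and the 4 pairs that mix genotypes gave between 1010 and 3277. By midpoint, few K700E-only regions lay at a gene end (157 of 8213, 1.91%), compared with 134 of 1620 (8.27%) of WT-only regions and 12.9% of regions in all 4 libraries. The strongest K700E-only regions outside gene ends were chromosome 18, 761401 to 776800, inside YES1, a SRC-family kinase gene, with 290 and 427 reads. The next were chromosome 22, 11240401 to 11248400, whose nearest protein-coding gene, OR11H1, is 4279791 bp away, with 279 and 251 reads, and chromosome 14, 18655001 to 18672800, 52903 bp from OR11H12, with 272 and 235 reads. The strongest WT-only regions were chromosome 10, 21171401 to 21175600, inside NEBL, with 211 and 153 reads. They were followed by chromosome 2, 77976601 to 77978200, 454224 bp from LRRTM4, with 175 and 120 reads, and chromosome 21, 23921601 to 23924600, 1661055 bp from MRPL39, with 181 and 91 reads. The excess depended on the length of the lists: with 81251 islands taken from each library, K700E-only regions numbered 4652 and WT-only regions 3983, a ratio of 1.17 in place of 5.07, while 2.06% and 7.66% of them lay at gene ends. Leaving out any 1 library, which loosens what counts as specific to a genotype, gave 11591 to 25197 and 2739 to 5860.

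**Figure D2:**
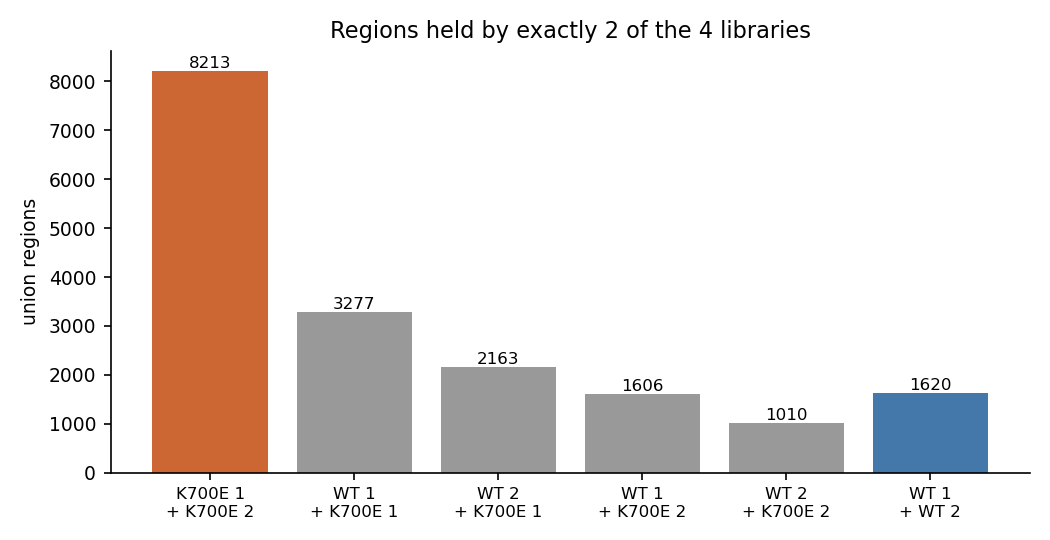
Number of union regions held by exactly 2 of the 4 libraries, for each pair of libraries. The pair of K700E libraries shares 8213 regions that neither WT library holds, above each of the 4 mixed pairs (grey) and the WT pair, at 1620.

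The island sets overlapped to a similar degree within and between genotypes. The Jaccard index was 0.529 for the WT pair and 0.589 for the K700E pair, and 0.580, 0.560, 0.484 and 0.461 for the pairs of different genotype. The mean within genotypes exceeded the mean between them by 0.0377, and the other 2 ways of splitting the libraries gave -0.0200 and -0.0178. Without K700E replicate 2 the difference was -0.00282, and without WT replicate 1 it was 0.117. Reads separated the genotypes more than presence did. Over the 32604 islands that correspond 1 to 1, the Pearson correlation of log CPM was 0.922 for the WT pair and 0.894 for the K700E pair. For the pairs of different genotype it was 0.873, 0.836, 0.832 and 0.792.

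At the level of genes, 14109 and 13930 of 19970 protein-coding genes had a gene-end island in the WT libraries and 14448 and 14106 in the K700E libraries, with 12795 in all 4 and 4440 in none. The mean difference was 257.5 genes (exact permutation p = 0.667) and turned to -118.5 with equal numbers of islands and -97.5 in the stronger part of each list. It was 86.5 without K700E replicate 1, 168 without WT replicate 2, 428.5 without K700E replicate 2 and 402 with whole gene bodies. K700E-only genes numbered 244 and WT-only genes 149, against 70 to 121 in the mixed pairs; with equal numbers of islands, 185 and 300. Leaving out any 1 library gave 396 to 605 and 274 to 532, and whole gene bodies gave 88 WT-only genes. Part of these calls came from where an island's edge fell: the islands of 73 of the 244 K700E-only genes and 18 of the 149 WT-only genes belonged to regions that both libraries of the other genotype also held.

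This applied to all of the 10 K700E-only genes with the strongest islands, TSKS, SEZ6, MACC1, ZNF469, APOA2, MUC6, SLC5A8, ADHFE1, GIMAP4 and FBXW10. At MACC1, for example, the K700E islands held 849 and 653 reads and reached the window, while the WT islands of the same region held 930 and 630 reads and ended outside it. Of the 10 strongest WT-only genes, it applied to XIRP1, CRYAB, VIPR2, FGF8, ZFAND4, GLS2 and HLA-DQB1. The islands of CKAP4, EBF4 and LOC124902420 had no counterpart in K700E. CKAP4, which encodes an endoplasmic reticulum membrane protein, held 184 and 90 reads in WT. EBF4, a transcription factor gene of the early B-cell factor family, held 157 and 107, and LOC124902420 held 225 and 110. Among K700E-only genes whose region no WT library held, chosen after their values were seen, TMPRSS4, a membrane serine protease gene, had 156 and 188 reads and KLRF1, a natural killer cell receptor gene, 190 and 140.

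Nearly all genes of the lists for housekeeping and nuclear functions had a gene-end island in every library. All 42 splicing genes and all 77 ribosomal protein genes had one in every library. So did 29 of 30 R-loop genes, 43 of 45 elongation genes, 25 of 26 H3K4 methylation genes, 32 of 33 SIN3 and HDAC genes, 49 of 52 replication genes, 51 of 54 replication stress and repair genes and 24 of 27 genes mis-spliced with mutant SF3B1. Of the lineage lists, 44 of 52 erythroid genes had an island in all 4 libraries, 10 of 23 megakaryocyte, 11 of 25 granulocyte and monocyte, 14 of 26 stem and progenitor, 25 of 41 interferon and inflammation, 9 of 22 lymphocyte, 8 of 20 epithelial, 1 of 20 hepatocyte and 7 of 22 neuron genes. Of 36 tests, 0 passed after adjustment and 1 had an unadjusted p under 0.05. It was for neuron genes in the WT-only direction, 2 of 9 (RBFOX3 and SYT1; Fisher's exact p = 0.00417, adjusted p = 0.150), and it passed without WT replicate 1, at 3 of 10 (adjusted p = 0.0397). The other WT-only members were MLLT3, a stem-cell and elongation gene, with 66 and 34 reads in WT, and THOC7, of the mRNA export complex THO, with 74 and 48. The K700E-only members were GP1BA, a platelet receptor gene, with 56 and 118 reads in K700E, CD3G, a T-cell receptor gene, with 71 and 74, APOH with 29 and 36, and APOA2, where the WT libraries held the same region. Of the first members of the other lists, KLF1, MAP3K7, MCM2, MCM3, ATR, ATRIP, SF3B2, KMT2A, KMT2B, HDAC1, HDAC2, RPL3 and RPL4 had a gene-end island in all 4 libraries. MPO and CDH1 had none. The mean length covered in the gene-end windows was 799.9 ± 8.40 bp in K700E and 747.9 ± 57.7 bp in WT over all protein-coding genes (SD, n = 2; exact permutation p = 0.333). The difference of 52.0 bp was 11.2 bp without WT replicate 2 and 92.9 bp without WT replicate 1. Over the gene lists the difference ranged from -62.1 bp for neuron genes to 185 bp for epithelial genes (712 ± 77.9 and 527 ± 165 bp). It was 181 bp for lymphocyte genes (581 ± 37.9 and 400.3 ± 145 bp) and 125 bp for splicing genes (1404 ± 31.2 and 1279 ± 47.3 bp).

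Where the same island was present in all 4 libraries, reads at gene ends were lower in K700E. Over 6986 gene-end islands, here by overlap and not by midpoint, the median log2 fold change was -0.49. It was 0.15 over the 25618 other islands, 0.12 inside protein-coding genes and 0.17 between genes. The median gene-end island held 23.4 ± 1.23 CPM (counts scaled to the normalised library size) in K700E and 33.0 ± 1.28 in WT, and the median other island 16.0 ± 0.104 and 14.1 ± 1.02 (SD, n = 2; exact permutation p = 0.333 for each). Scaling to the total reads of the shared islands moved the median of all islands from 0.04 to 0.23. The gene-end median was then -0.29 and that of other islands 0.34. Shared islands held 9467030 and 6007450 reads in WT and 9354840 and 7542720 in K700E, a smaller share of all island reads in both K700E libraries. Scaling to all island reads was not run. The gene-end difference relative to other islands lay between -0.50 and -0.76 on the log2 scale in the 4 comparisons of a K700E with a WT library, and was 0.12 between the WT libraries and -0.10 between the K700E libraries. The mitochondrial share of reads, 5.44% ± 0.594 in K700E and 7.95% ± 1.97 in WT (SD, n = 2), differed between the same libraries.

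**Figure D3:**
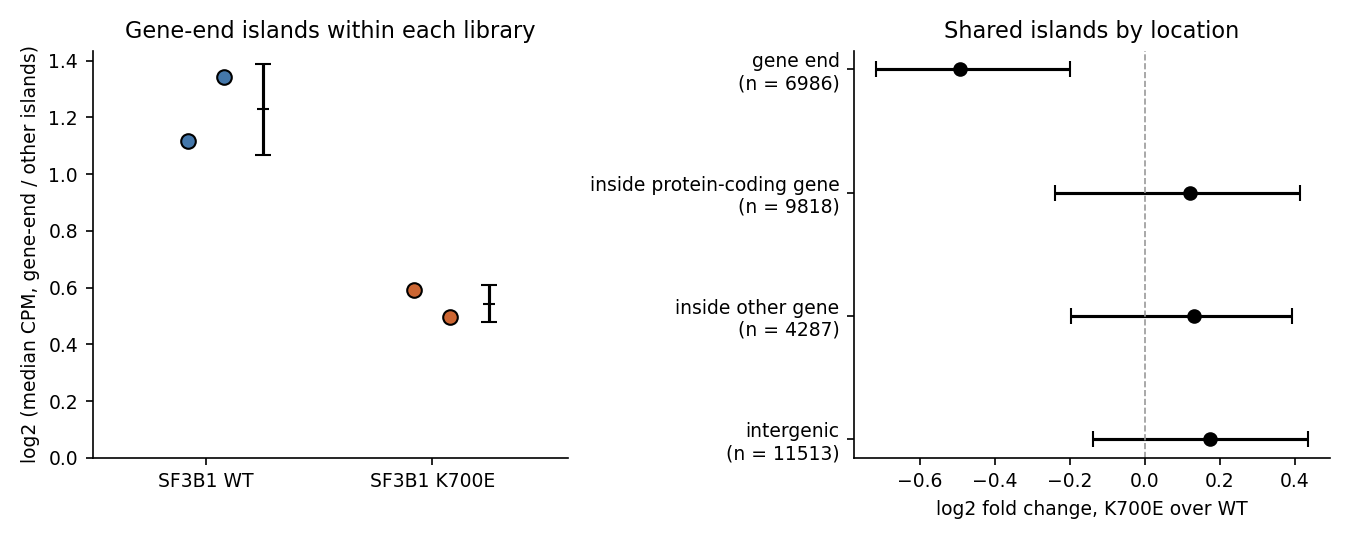
Left, log2 ratio of the median CPM of gene-end islands to that of other shared islands in each library (points), with the mean and SD of each genotype (bars, n = 2). Right, median (points) and quartiles (bars) of the log2 fold change across islands, by location; the gene-end median is -0.49 and the intergenic median 0.17.

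By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1329 of 32604 shared islands were lower and 182 higher in K700E. Gene-end islands supplied 1030 of the lower and 19 of the higher islands. Among the lower islands with the smallest p, chosen after their values were seen, was that at PDCD6IP, an endosomal sorting gene (chromosome 3, 33795801 to 33801000; log2 fold change -1.68 ± 0.13 SE, adjusted p = 0.0191). Others were those at CHPT1, a phosphatidylcholine synthesis gene, whose island also serves MYBPC1 (-2.07 ± 0.20), CLASP2, a microtubule-binding gene (-1.55 ± 0.14), MCU, the mitochondrial calcium uniporter gene (-1.53 ± 0.15), and the shared island of the mitochondrial chaperonin genes HSPD1 and HSPE1 (-1.29 ± 0.13). The islands at PDCD6IP and CLASP2 lay on chromosome 3, that at MCU on 10 and that at CHPT1 on 12, the chromosomes left out in a separate fit. That at HSPD1 and HSPE1 lay on chromosome 2. With regional offsets all of these islands still passed. XIRP1, named above, fell from 349 and 226 reads to 118 and 62 (log2 fold change -2.03 ± 0.27 SE, edgeR adjusted p = 0.0197). The higher islands with the smallest p, likewise chosen after their values were seen, touched no end of a protein-coding gene. They lay on chromosome 16 from 33731601 to 33746400 (1.19 ± 0.15), chromosome 19 from 44719601 to 44727800 (2.11 ± 0.29) and chromosome 8 from 48939201 to 48946800 (1.84 ± 0.26). The split of calls depended on scaling: 37 higher and 123 lower with scaling to the total, and 400 higher and 596 lower with loess offsets. Leaving out WT replicate 1 gave 245 higher and 350 lower, and leaving out K700E replicate 2 gave 39 and 403. Without WT replicate 2, edgeR called 0 islands, with 1465 higher and 3898 lower at an unadjusted p under 0.05. DESeq2 on all 4 libraries called 492 and 2055, and the replicate block gave 611 and 2110.

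Of all gene-end islands, 83.8% had a log2 fold change below 0 and 14.7% were called lower, the background for the lists below. Adjustment over a list alone was not run on other sets of gene-end islands, so those counts have no such background. Calls on single members of the fixed lists depended on the setting. Of 36 calls on list members, counting a gene once per list, DESeq2 gave 36 again, scaling to the total gave 1 (AFF1) and loess offsets 16. Leaving out WT replicate 1 gave 11, leaving out WT replicate 2 gave 0, leaving out K700E replicate 1 gave 29 and leaving out K700E replicate 2 gave 9. Of 25 islands at elongation genes, all 25 lay below 0 and 7 passed as lower (18 adjusted over the list alone), among them AFF1, of the super elongation complex (-1.16 ± 0.14 SE, edgeR adjusted p = 0.0191). POLR2B, an RNA polymerase II subunit gene, gave -0.76 ± 0.14 and did not pass with loess offsets. NELFA, of the pausing factor NELF, gave -0.93 ± 0.21 and did not pass with loess or regional offsets. Of 18 islands at genes mis-spliced with mutant SF3B1, 5 were lower (8 adjusted over the list alone), led by BRD9, of a BAF chromatin remodeller, whose island also serves TRIP13 (-1.35 ± 0.20, edgeR adjusted p = 0.0212). Its adjusted p was 0.0536 with regional offsets, and from 0.00013 with DESeq2 to 0.122 without WT replicate 2 over all settings. DYNLL1, a dynein light chain gene, gave -1.01 ± 0.15 at an island that also touched SRSF9. Other islands of this paragraph touched a second gene too: AFF1 (C4orf36), POLR2B (NOA1), NELFA (LOC124900839), RAD1 (BRIX1), FANCF (GAS2) and DDX21 (KIFBP). Of 40 islands at replication stress and repair genes, 39 lay below 0 and 4 were lower (20 adjusted over the list alone): RAD1, FANCF, DNA2 and WEE1. With regional offsets DNA2 (edgeR adjusted p = 0.0644) and WEE1 (0.0529) did not pass. With loess offsets FANCF (edgeR adjusted p = 0.0510) and WEE1 (0.183) did not pass. RAD1 passed with both. Lower islands also included 2 of 34 at replication genes (12 over the list alone) and 3 of 18 at R-loop genes (7), with DDX21, an RNA helicase gene, at -1.10 ± 0.15. They included 4 of 25 at SIN3 and HDAC genes (15, with 1 higher, over the list alone), with SAP30L at -1.06 ± 0.17, 3 of 20 at H3K4 methylation genes (12), 1 of 31 at splicing genes (14) and 2 of 19 at ribosomal protein genes (7). The 3 lower R-loop islands, at DDX21, DDX23 and ATXN2, lay on chromosomes 10 and 12. With regional offsets DDX21 passed (edgeR adjusted p = 0.0248), while DDX23 (-0.45, edgeR adjusted p = 0.134) and ATXN2 (-0.93, edgeR adjusted p = 0.0863) did not.

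Among 22 erythroid islands, MYB, a progenitor transcription factor gene, and PPOX, a haem synthesis gene, were lower (2 over all islands, 5 adjusted over the list alone). The PPOX island also touched B4GALT3 and USP21. The island at TAL1, an erythroid transcription factor gene, was higher (log2 fold change 1.55 ± 0.30 SE, edgeR adjusted p = 0.0346). It held 8.91 and 12.8 CPM in WT and 36.9 and 25.8 in K700E. The TAL1 island spanned chromosome 1 from 47208001 to 47219800 and was not among the islands with matching extents. Its counts therefore refer to stretches that differ between libraries. Whether it lay at the start or at the end of TAL1 was not determined. TAL1 did not pass with scaling to the total (adjusted p = 0.0530 by edgeR) or when any 1 library was left out (0.0518 to 0.122), and the smallest adjusted p of the settings was 0.000807, by DESeq2. MYB was also the lower member of 12 stem and progenitor islands (7 over the list alone), and STAT2 that of 13 interferon islands (6, with 1 higher). The STAT2 island, which also touched APOF, lay on chromosome 12 between 45 and 60 Mb, a segment where islands were lower together. The 4 neuron islands gave 0 calls (1 over the list alone). The lists of other cell types had few shared islands, 5 megakaryocyte, 6 granulocyte and monocyte, 5 lymphocyte, 2 epithelial and 3 hepatocyte, and none passed in either direction. Of the reference genes, the HBG1 island gave -1.01 ± 0.35 (edgeR adjusted p = 0.125, and over the settings 0.0181 without K700E replicate 1 to 0.281 without WT replicate 2). It passed with DESeq2 (adjusted p = 0.0473) and with the replicate block (0.0312). The SF3B1 island gave -0.72 ± 0.28 (edgeR adjusted p = 0.159), while GATA1 and GAPDH had gene-end islands in every library but none that corresponded 1 to 1. The strongest GATA1 island lay at the end of the gene with the lower coordinate in both WT libraries and at the other end in both K700E libraries, so its reads were not compared.

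No list differed from the other gene-end islands after adjustment. By camera the smallest adjusted p of the 18 lists was 0.230, for elongation genes (median -0.54) and for granulocyte and monocyte genes (median -0.05, and 0.15 with scaling to the total). At an unadjusted p under 0.05 there were 2, these lists, and the adjusted p was 0.978 with an estimated correlation.

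**Figure D4:**
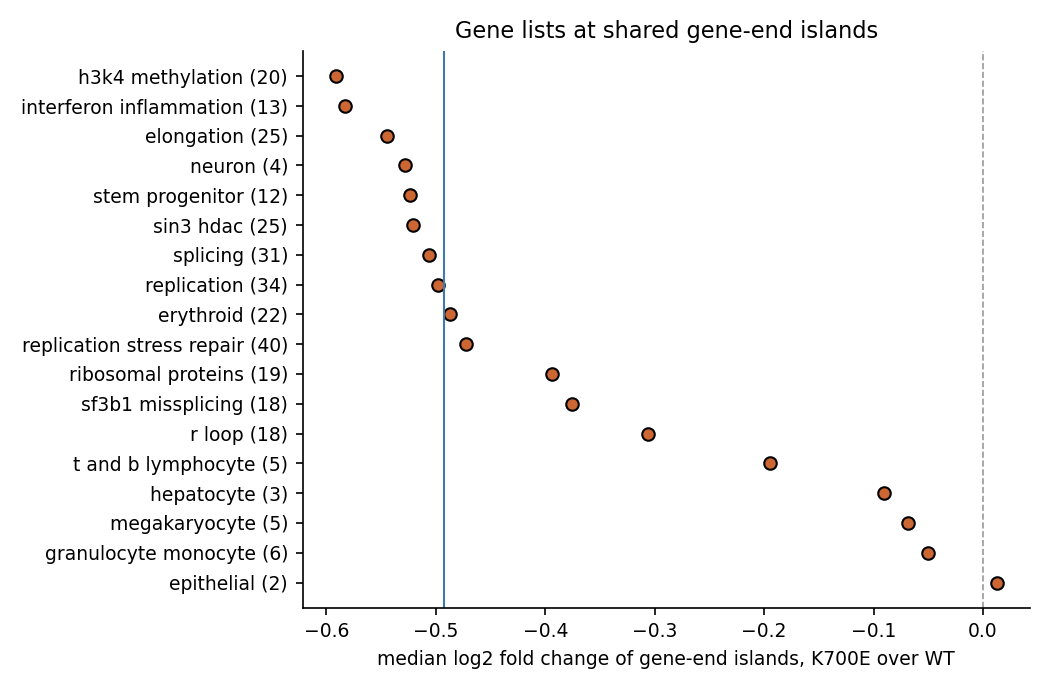
Median log2 fold change, K700E over WT, of the shared gene-end islands of each gene list (points; number of islands in brackets); lists with many islands lie near the blue line, the median of all gene-end islands (-0.49), and the dashed line marks 0. With scaling to the total reads of the shared islands, the medians of the megakaryocyte (0.15), granulocyte and monocyte (0.15), hepatocyte (0.11) and epithelial (0.21) lists lie above 0. With loess offsets that of the hepatocyte list (0.10) does and that of the epithelial list (-0.08) lies below 0.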

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

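All tests in this part were chosen after the results were seen, except those of gene density and of 5 Mb bins.

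Sequences outside the autosomes and X, which entered only the setting with all sequences, held more islands in K700E, a mean of 610.5 against 513 in WT, a ratio of 1.19 beside 1.20 on the autosomes and X.

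K700E libraries held more islands and 5.07 times as many K700E-only as WT-only regions. A floor in RPM that differs between libraries is argued against: with a common floor of 2 RPM, above the weakest island of every library, the ratio was 4.28. The lists stayed unequal, with 79623 and 78432 islands in WT and 95933 and 89366 in K700E. The lowest score was 38.3 and 24.9 in WT and 32.1 and 35.2 in K700E and was not equalised, so an unequal cutoff on the score stays open. With 81251 islands from each library the ratio was 1.17, which the equal lengths impose in part. A flatter signal in K700E stays open. The 10000 strongest islands held a smaller share of reads in both K700E libraries, the higher of which lay 4.77 percentage points below the lower WT library, and since this difference runs with genotype it cannot be told apart from a change in chromatin. Whether longer lists arose from library quality or from the mutation is not resolved by 2 libraries per genotype, since the mitochondrial share of reads also ran with genotype (5.02% and 5.86% in K700E, 6.55% and 9.34% in WT).

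Gene-end islands held fewer reads in K700E relative to other islands. A loss of reads set only by how many reads an island held is argued against as the whole cause. In each of the 4 stronger of 5 groups of islands by strength, gene-end islands lay at least 0.41 (log2) below other islands (values from -0.41 to -0.68). In the weakest group the value was -0.16. Strength was taken from the reads of the whole island. A loss from islands dense in reads per base pair was therefore not tested and stays open. Different extents of islands are argued against as well for the islands with matching extents, where the difference was -0.66. These included 533 of the 6986 gene-end islands. A bias against GC-rich sequence remains open: no genome sequence was used, and the substitute, islands outside gene ends in gene-dense against gene-poor surroundings, gave -0.0592, a smaller size than the 0.0898 seen between the K700E libraries. Lower accessibility at gene ends with SF3B1 K700E is a hypothesis that these data may fit, alongside differences in transposition or fragment selection that follow genotype.

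Several of the lowest islands lay close together, as on chromosome 12 between 45 and 60 Mb, where 57 of 243 islands were lower and 0 higher. Unequal copy number between the cell populations is a candidate explanation, which predicts a like shift of all islands of a segment. In that segment gene-end islands shifted by -0.40 and other islands by -0.19 against their classes elsewhere, a ratio of 2.13 with a 95% bootstrap interval of 1.17 to 7.51. Over 18 bins of 5 Mb chosen on weak islands, the shift of strong over held-out weak islands was 1.27, with an interval from -5.33 to 7.03, because the held-out shift was only 0.05. Copy number and accessibility cannot be told apart here, since the second interval spans both signs and the first, though above 1, begins close to a like shift.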

How the results depend on the processing

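Count tests, the gene-end contrast, the floor of 2 RPM and whole gene bodies were chosen after the data had been seen. Causes were not tested unless stated. With equal numbers of islands, K700E-only regions fell to 4652 and WT-only regions rose to 3983, which the equal lengths impose in part; the gene-end share differed by -1.26 points, the number of genes with a gene-end island by -118.5, in the opposite direction, and WT-only genes numbered 300. In the stronger part of each list the values were 8258 for the difference in islands, 4337 and 886 for K700E-only and WT-only regions, -4.99 points, -97.5 genes, again opposite, and 274 WT-only genes. Whole gene bodies gave 88 WT-only genes and a difference of 402 genes. The other settings, each run for part of the results, stayed within the spread or within 1.5 times: all sequences (islands, covered length, regions, similarity), islands of at least 400 bp (islands, covered length, similarity), stricter overlap (regions, genes, lists), merging within 1 kb (regions), gene-end windows of 500 bp and 2 kb (location, genes, lists) and the floor of 2 RPM (all of these and breadth). Leaving out 1 library leaves an arm of 1 and loosens what counts as specific to a genotype: K700E-only regions ranged from 11591 to 25197, WT-only regions from 2739 to 5860, K700E-only genes from 396 to 605, WT-only genes from 274 to 532, the similarity difference from -0.00282, without K700E replicate 2, to 0.117, and list calls from 0 to 1. The difference in islands ranged from 9964.5 to 23066.5, in covered length from 49885000 to 131456000 bp, in genes from 86.5 to 428.5, in location from -3.37 to -1.68 points and in gene-end cover from 11.2 to 92.9 bp. Higher and lower shared islands ranged from 0 to 251 and from 0 to 1813; the lone library was assumed to vary like the others. They numbered 37 and 123 with total scaling, 400 and 596 with loess offsets, and 492 and 2055 with DESeq2. They numbered 273 and 981 over all regions of the 4 lists, 241 and 1315 with regional offsets, and 182 and 1329 with no filter. At matching extents they were 92 and 694 of 5058 islands tested, a larger share lower than the 1329 of 32604 in the main fit. Of the calls in the main fit, only 2 higher and 114 lower were made again there. Main calls on islands without matching extents could not be. Without chromosomes 3, 10 and 12 the higher and lower islands numbered 115 and 833 of 27382. Leaving these chromosomes out took away a larger share of the lower calls than of the islands tested. How they were chosen is not stated, and most of the lower islands with the smallest p lay on them. The larger loss of lower calls is therefore not an independent result. The gene-end contrast was -0.64, kept its sign under every setting run, and moved to -0.49 with loess offsets and -0.46 per base pair of island; leaving out a library gave -0.57 to -0.70. The replicate numbers are not stated to pair the libraries, and the deviations of the replicates correlated at -0.03 across islands. With the replicate block the count test gave 611 and 2110, and the differences were 16515.5 islands, 90670400 bp, -2.53 points, 257.5 genes, 52.0 bp of gene-end cover and -0.64 for the contrast. For the 28 named genes held by different numbers of K700E and WT libraries, 135 of 196 comparisons with another setting kept that difference, 61 made it smaller and 0 reversed it. All sequences were not run for gene-based results. A single start site per gene was not run, since the gene table has no strand. Depth limits weak islands most: 17 to 28 reads was the weakest reported.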

Other observations

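The tests of gene families and gene length were set before their results were seen, but the comparison of gene-end islands they build on was chosen after.

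Gene families chosen by symbol had medians from -0.28 to -0.49, against -0.49 over all gene-end islands, and each stayed below 0 with total scaling (-0.30 to -0.08), loess offsets (-0.37 to -0.10), regional offsets and DESeq2; family medians under these settings were chosen after the data had been seen. The median log2 fold change was -0.41 over 285 islands at ZNF zinc finger genes, with 24 lower and 1 higher, -0.41 over 22 at histone genes, -0.36 over 43 at mitochondrial ribosomal protein genes, -0.45 over 31 at proteasome genes, -0.49 over 32 at complex I genes and -0.28 over 16 at tRNA synthetase genes. The hypothesis that families differ was negative at this threshold: the smallest adjusted p by camera was 0.523, and 0.915 with an estimated correlation.

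The hypothesis that gene-end islands of long genes were lower by more had a positive result. Across 6986 gene-end islands, which are not independent replicates, the Spearman correlation of gene length with log2 fold change was -0.19. The median log2 fold change was -0.37 for the shortest 1398 (median gene 8.28 kb) and -0.57 for the longest 1397 (median gene 178 kb). The correlation lay between -0.17 and -0.19 when 1 library was left out, was -0.26 at matching extents, and was 0.06 between the WT libraries and -0.05 between the K700E libraries. It was -0.04 among the weakest islands and -0.15 to -0.22 in the other 4 groups of strength. A length-dependent change at gene ends may therefore accompany the genotype in these libraries, though starts and ends of genes could not be separated, and GC content was not tested.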
